A study of Homo sapiens with 6 samples.

How the data were processed

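RNA sequencing was used to compare A2780 cells, a human ovarian cancer cell line, after transfection with an siRNA against MEX3A (si-MEX3A) or a negative control siRNA (si-NC). MEX3A encodes an RNA-binding protein with KH domains and a RING finger. Each group held 3 libraries, numbered 1 to 3 in the labels. Total RNA was extracted with Trizol and libraries followed the standard Illumina procedure, per the labels' protocols. The labels do not say whether the numbers mark separate cultures, separate days or separate siRNAs, so the p-values measure only the spread between these libraries, which may be technical.

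The submitters' processing notes name HISAT2, Cufflinks and the hg19 build, with no versions. The read counter, the gene annotation, the strand setting and the differential expression tool are not given in the sources used here. The deposited table held 305 genes, each with an Ensembl ID, a symbol, a count per library and the authors' comparison. Counts are whole reads per gene, not normalized, per the file headers and the values (5 to 34562 reads per gene and library). The authors' log2 fold change compares si-MEX3A with si-NC, and the authors' p-values come in a raw and an adjusted column, per the file headers. Every row had an adjusted p of at most 0.05 (largest 0.04999) and an absolute log2 fold change of at least 0.585 (a 1.50-fold change), so the authors had filtered the table on both before deposit. Unchanged genes, and changed genes below that fold, were not analysed here. At the smallest p-values the ratio of adjusted to raw p implies that the authors adjusted over 13076 genes. At the largest listed p it implies that about 2559 genes were at or below that adjusted p before the fold filter.

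The total depth of each library is unknown, because the table holds only part of each library. The listed genes held 313928, 289380 and 325377 reads in si-NC libraries 1 to 3 and 233923, 231468 and 257838 reads in si-MEX3A libraries 1 to 3. These sums move with the genes chosen and were not used for scaling. Instead, 1 scale factor per library was recovered by least squares, as the 6 factors (geometric mean 1) with which the ratios of mean scaled counts match the deposited log2 fold changes. The match had a root mean square difference of 0.00062 and a largest difference of 0.0055 log2 units. The factors were 0.993, 0.941 and 1.02 in si-NC and 0.984, 0.995 and 1.07 in si-MEX3A, with bootstrap SDs of at most 0.00145. On simulated counts the recovery was tested and missed the known factors by at most 0.145%. Levels below are counts divided by these factors, as mean ± SD over 3 libraries.

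Fold changes and standard errors (SE) come from edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, 2 groups, no covariate, no filter, effective library sizes from the recovered factors), with Benjamini-Hochberg adjustment over the 305 rows. The SE is the absolute log2 fold change divided by the square root of the test's F. This test runs on genes already chosen for differing, so it is not independent evidence. A gene is called higher or lower on the authors' adjusted p, and the edgeR values give its size and error. The plan had assumed edgeR's TMM scaling. TMM assumes that most genes in the table are unchanged, which this table's construction rules out, so TMM and DESeq2 size factors are given as alternatives. On counts simulated for this comparison over 305 genes, edgeR found 98.0% of 50 genes changed 1.5-fold and 100% of 50 changed 2-fold. It also called 5.70% of 105 unchanged genes. The simulated spread was taken from the listed genes, which were chosen for differing, so the recovery may be overstated. Unlike the real table, the simulated one held unchanged genes, and its changes were up or down at equal odds. Replicates were compared by chi-square tests of their counts, and every pair of a group differed by more than sampling noise (smallest chi-square per degree of freedom 1.81), so all 6 were treated as separate libraries. Same-numbered libraries of the groups were not treated as pairs.

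Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for named genes were fixed. The named genes are MEX3A, the 12 with the highest and the 12 with the lowest deposited fold change among genes with a group mean of at least 50 counts, and up to 4 members of each list. Other genes named were chosen after their values were seen. The table gives no background of measured genes, so enrichment of a list in it was not tested. For each list with at least 3 members in the table, the direction of its members was set against that of the other rows by a two-sided Fisher's exact test, adjusted over the 7 lists tested. Genes are not independent replicates, so these p-values describe the table and do not measure the spread between libraries. A list member absent from the table was either unchanged, changed less than the filters ask, or not measured.

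Gene positions and types come from GENCODE 29 (GRCh38), matched on Ensembl ID for 303 of the 305 genes. The table itself gives no coordinates, and none were converted. Of the listed genes, 151 overlap another annotated gene on the opposite strand and 88 overlap one on the same strand. With the strand setting not given, reads of such genes cannot always be told apart. The 3′ UTRs of protein-coding genes were taken from 1 basic GENCODE transcript per gene, an APPRIS principal one where there was one and among those the one with the longest 3′ UTR, and searched for every 7-base word. Each listed gene was matched to the 60 nearest of 18647 unlisted protein-coding genes in 3′ UTR length and GC content. Of the 7-base words, 12640 were expected in more than 5 of the lower genes and were ranked by z, and 1000 random sets drawn from the matched genes gave the highest z reached by chance. In a test on simulated data, each of 5 words planted in 20% of a random gene set came first. Python 3.11.15 with scipy 1.17.1, and DESeq2 1.42.0, were also used. The search for words was designed after the table had been seen. The alternatives were TMM and DESeq2 scaling, no scaling, a minimum mean count, stricter thresholds, a replicate block and leaving out each library in turn. Pseudocount and trend settings planned for FPKM values did not apply to counts.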

Results

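The data hold 305 genes that the authors called changed between 3 si-MEX3A and 3 si-NC libraries of A2780 cells. By the authors' deposited table, 224 of them were lower and 81 higher after the knockdown, so 73.4% were lower (95% Clopper-Pearson interval 68.1 to 78.3%, which covers counting error only; exact binomial test against an even split, two-sided p = 1.15e-16, as a description of the list). With scale factors taken from the listed genes themselves, 47.7% (edgeR's TMM) and 45.6% (DESeq2) of the genes called were lower. These factors shift the log2 scale of si-MEX3A over si-NC by -0.66 (TMM) and -0.67 (DESeq2). Every gene's fold change rises by nearly that amount, so a fall of that size lands close to 0. A call lost with these factors, here and below, therefore does not decide whether the gene fell. The listed genes held 231468 to 325377 reads per library, and total depth is unknown. By GENCODE type, 275 were protein-coding (209 lower, 66 higher), 12 were long intergenic noncoding RNAs (4 lower, 8 higher) and 2 were small nucleolar RNAs, both higher. The median deposited log2 fold change was -0.77 among the lower genes and 0.80 among the higher ones. At least a 2-fold change was seen in 54 lower and 26 higher genes. In 304 of the 305 genes the 3 si-MEX3A libraries lay wholly above or below the 3 si-NC libraries, where chance gives 10% of unselected genes. The exception was AC099850.3. The median SD of log2 counts between libraries was 0.107 in si-NC and 0.090 in si-MEX3A.

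The first question is whether the target of the siRNA fell. MEX3A (ENSG00000254726), on chromosome 1 from 156072013 to 156081998 on the minus strand of GRCh38, had 883 ± 36.1 scaled counts in si-NC and 398 ± 19.6 in si-MEX3A (SD, n = 3 each). It was left at 45.1% of its control level, a log2 fold change of -1.15 with an SE of 0.07. The adjusted p in the authors' deposited table was 1.18e-37. An exact two-sided permutation test of the 3 against 3 libraries gave p = 0.1, the smallest that this design allows. All 3 si-MEX3A libraries lay below all 3 si-NC libraries. With TMM factors from the listed genes the log2 fold change was -0.49. MEX3B, MEX3C and MEX3D, the other members of the family, were not among the listed genes.

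The second question is which genes rose with the knockdown. Immediate early genes, which growth factors and stress induce within minutes, rose together. Of the 30 genes on that list 12 were in the table and all 12 were higher, against 69 higher and 224 lower among the other rows (Fisher's exact test, adjusted p = 4.56e-07, as a description of the table). FOS, a subunit of the AP-1 transcription factor, rose from 136 ± 20.5 to 358 ± 27.2 scaled counts (SD, n = 3), a log2 fold change of 1.39 with an SE of 0.12. FOSB rose by a log2 fold change of 1.22 with an SE of 0.13. ATF3, a stress-induced transcription factor, rose from 68.9 ± 18.9 to 188 ± 20.7, and EGR3 rose from 89.7 ± 27.8 to 187 ± 14.1 (SD, n = 3). The other 8 members, with log2 fold changes from 0.59 for FOSL1 to 0.98 for EGR1, were DUSP1, DUSP5, EGR1, FOSL1, FOSL2, JUNB, NR4A1 and SPRY4. All 12 also passed when adjusted over the list alone, with each deposited p multiplied by the list's full length. Every listed gene had already passed the authors' adjustment over 13076 genes, so this adds no support. The mean log2 count of the 12 genes was 8.32, 8.28 and 7.93 in si-NC libraries 1 to 3 and 9.20, 9.05 and 9.06 in si-MEX3A libraries 1 to 3. si-NC replicate 3 was the lowest of the controls, and the difference of the group means was 0.92 with it and 0.80 without it.

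**Figure D1:**
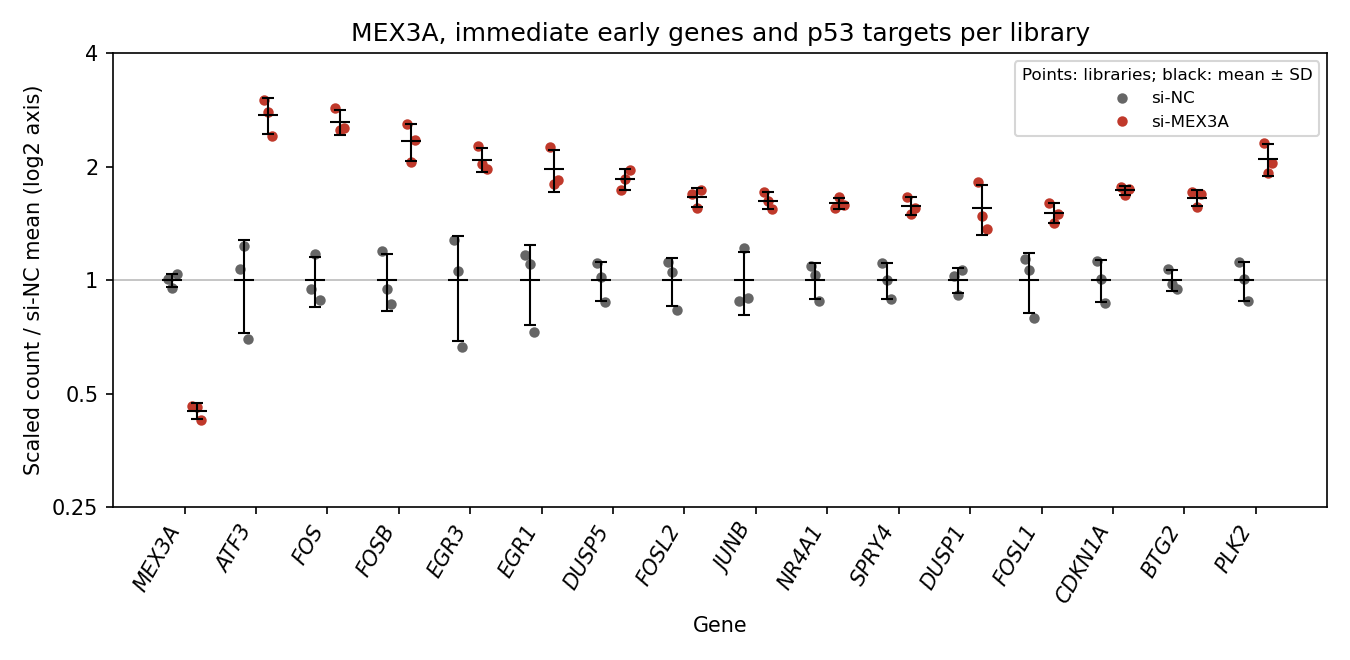
Scaled count of each library divided by the si-NC mean (log2 axis) for MEX3A, the 12 immediate early genes in the table and the 3 p53 targets. Coloured points are the 3 libraries of each group and black bars are mean ± SD. MEX3A sits at 45.1% of the control level, and the other genes lie above their controls in all 3 si-MEX3A libraries.

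Genes activated by p53 were represented by 3 of 40 list members, and all 3 rose (Fisher's exact test, adjusted p = 0.043). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had the most reads of the genes in the table, with no correction for transcript length. It rose from 18472 ± 2351 to 31957 ± 861 scaled counts (SD, n = 3), a log2 fold change of 0.79 with an SE of 0.08. BTG2, an antiproliferative gene, rose from 3556 ± 229 to 5885 ± 281, and PLK2 rose from 248 ± 29.2 to 520 ± 50.4 (SD, n = 3). The 3 listed hypoxia and glycolysis genes also rose (adjusted p = 0.043). They were ADM, which encodes adrenomedullin, with a log2 fold change of 1.51 (SE 0.20), ANKRD37 with 1.47 (SE 0.27) and the glucose transporter gene SLC2A3 with 0.86 (SE 0.05). With TMM factors from the listed genes neither 3-gene list passed (Fisher's exact test, adjusted p = 0.25 for each). Nor did they when genes with the 3′ UTR site described further on were left out of the table (adjusted p = 0.22 for each). All 3 members of each list stayed higher in both settings. Against the near-even split of the rows left there, 3 of 3 higher cannot pass, so these settings could not test the 3-gene lists. The immediate early genes passed in both settings (adjusted p = 0.0014 and 0.0013). The hypoxia list held 28 genes in all.

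The gene with the largest rise was DUSP8, a phosphatase gene acting on MAP kinases, from 7.78 ± 0.31 to 52.2 ± 12.01 scaled counts (SD, n = 3), a log2 fold change of 2.72 with an SE of 0.30. SNORD3B-1 and SNORD3A, copies of the U3 small nucleolar RNA, rose by log2 fold changes of 2.04 (SE 0.32) and 1.72 (SE 0.27). Their sequences are near-identical, so the split of reads between them is uncertain. The list of small noncoding RNA genes held these and MIR600HG, a host gene that was lower (log2 fold change -0.62, SE 0.16; 0.05 with TMM factors from the listed genes), and did not differ in direction from the other rows (adjusted p = 0.24). The remaining genes among the 12 largest rises were HTRA3, a secreted serine protease gene, with a log2 fold change of 1.51 (SE 0.21), ABCC3, a transporter gene, with 1.30 (SE 0.20), CHGA, which encodes chromogranin A, with 1.18 (SE 0.24), and the noncoding LINC00942 with 1.15 (SE 0.25).

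Ferroptosis and glutathione genes were represented by 2 of 31 list members, too few for a test of direction. SLC7A11, the cystine importer of glutathione synthesis, rose from 692 ± 113 to 1144 ± 87.3 scaled counts, and CHAC1, which degrades glutathione, rose from 196 ± 28.3 to 413 ± 44.6 (SD, n = 3). The list of unfolded protein and integrated stress response genes held 3 that rose (ATF3, CHAC1 and SLC7A11) and 2 that fell, SDF2L1 with a log2 fold change of -0.94 (SE 0.11) and CEBPG with -0.71 (SE 0.07). Its direction did not differ from the other rows (adjusted p = 0.21). Among extracellular matrix and mesenchymal genes, MMP3 rose by a log2 fold change of 0.97 (SE 0.14) and the integrin gene ITGA5 by 0.79 (SE 0.05). Of inflammatory genes only RELB, an NF-kB subunit gene, was listed and it rose by 0.60 (SE 0.08). Among apoptosis regulators, CASP9 rose by 0.65 (SE 0.13) while BCL2, an inhibitor of apoptosis, had a log2 fold change of -0.69 (SE 0.09). With TMM and DESeq2 factors from the listed genes BCL2 (-0.03 and -0.02), CEBPG (-0.05 and -0.05) and SDF2L1 (-0.28 and -0.27) did not pass.

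The third question is which genes fell. Genes of DNA replication and the G1/S transition were represented by 5 of 47 list members, all lower, and genes of mitosis by 4 of 40, all lower, though CDC45, CDC6 and ECT2 had log2 fold changes just above 0 with TMM or DESeq2 factors from the listed genes, as HMMR had with DESeq2 factors. With both sets of factors RRM2 and NUSAP1 passed and the other 7 did not, E2F2 (-0.15 and -0.15), CLSPN (-0.03 and -0.02) and TOP2A (-0.01 and -0.01) included. The shift that these factors bring moves falls of this size close to 0 by itself, so it cannot decide whether those 7 changed. Since 73.4% of all rows were lower, neither list differed in direction from the other rows (Fisher's exact test, adjusted p = 0.38 and 0.58). RRM2, a subunit of ribonucleotide reductase, fell from 768 ± 26.3 to 364 ± 28.98 scaled counts, and the transcription factor gene E2F2 fell from 214 ± 12.5 to 122 ± 19.4 (SD, n = 3). CLSPN, CDC6 and CDC45 had log2 fold changes of -0.69 (SE 0.09), -0.65 (SE 0.06) and -0.60 (SE 0.08). NUSAP1, a spindle protein gene, fell from 687 ± 92.1 to 316 ± 28.1, and TOP2A, which encodes topoisomerase II alpha, fell from 4430 ± 376 to 2775 ± 148 (SD, n = 3). HMMR and ECT2 had log2 fold changes of -0.67 (SE 0.08) and -0.66 (SE 0.06). The interferon response list had 1 listed member, PARP14, at -0.62 (SE 0.06), which was also just above 0 with those factors.

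Among the 12 largest falls, PTPA, an activator of protein phosphatase 2A, fell from 2823 ± 48.6 to 831 ± 57.4 scaled counts (SD, n = 3), a log2 fold change of -1.76 with an SE of 0.06. ATP7A, a copper transporter gene, fell by 1.65 on the log2 scale (SE 0.13), and RPLP2, a ribosomal stalk protein gene, fell from 4991 ± 101 to 1645 ± 65.2. SHCBP1, ENDOD1 and VRK1 fell by 1.59 (SE 0.09), 1.52 (SE 0.17) and 1.46 (SE 0.08) on the log2 scale. STS, which encodes steroid sulfatase, fell by 1.43 (SE 0.19), RRS1 by 1.42 (SE 0.09) and DBI by 1.37 (SE 0.08). CDC42 fell from 4928 ± 173 to 1924 ± 172, and SRP14, of the signal recognition particle, fell from 3087 ± 153 to 1214 ± 32.4 (SD, n = 3). AC126474.2, whose coding status GENCODE leaves open, had 53.6 ± 7.55 and 17.3 ± 2.19 scaled counts. In all, 29 genes had a lower deposited fold change than MEX3A itself, and 10 of them lay below it by more than the 95% interval of the difference allows. RPLP2, CDC42 and SRP14 have pseudogene copies in the annotation, so their values are uncertain by any reads shared with those.

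The 3′ UTRs of the lower genes shared a short word. GATTAAA was present in 129 of 207 searched 3′ UTRs of lower genes (62.3%), against 22.1% expected from genes matched on 3′ UTR length and GC content. Its z was 15.4, where the highest z of any word exceeded 4.95 in 5% of 1000 random matched sets, and 0 of the 1000 sets reached it. The overlapping word AGATTAA followed, in 103 of the 207 (49.8%, expected 18.9%), and then TGATTAA in 89 (43.0%, expected 21.1%). GATTAAA or AGATTAA was present in 140 lower genes (67.6%, expected 29.5%), in 20 of the 27 searched genes that fell further than MEX3A (74.1%, expected 25.9%) and in 3 of 66 higher genes (4.5%, expected 14.1%). For the lower genes and for those below MEX3A, p was 0.001, the smallest that 1000 sets can give. These words had been picked for their excess in the same lower genes, and this p leaves out that choice. Those below MEX3A are a part of the lower genes and so add no separate support. Genes lower by less than 2-fold held a site in 66.9% (expected 31.3%). Of the lower genes named above, PTPA, ATP7A, SHCBP1, ENDOD1, VRK1, STS, RRS1, SRP14, RRM2, E2F2, ECT2, PARP14, SDF2L1, CEBPG and BCL2 held such a site. RPLP2, DBI, CDC42, CLSPN, CDC6, CDC45, NUSAP1, TOP2A and HMMR did not in the transcript searched. The 3 higher genes with a site were SLC7A11, FOSL2 and AKR1C1, of which AKR1C1 alone held the 8-base form. AKR1C1 has near-identical paralogs, so its reads are uncertain.

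**Figure D2:**
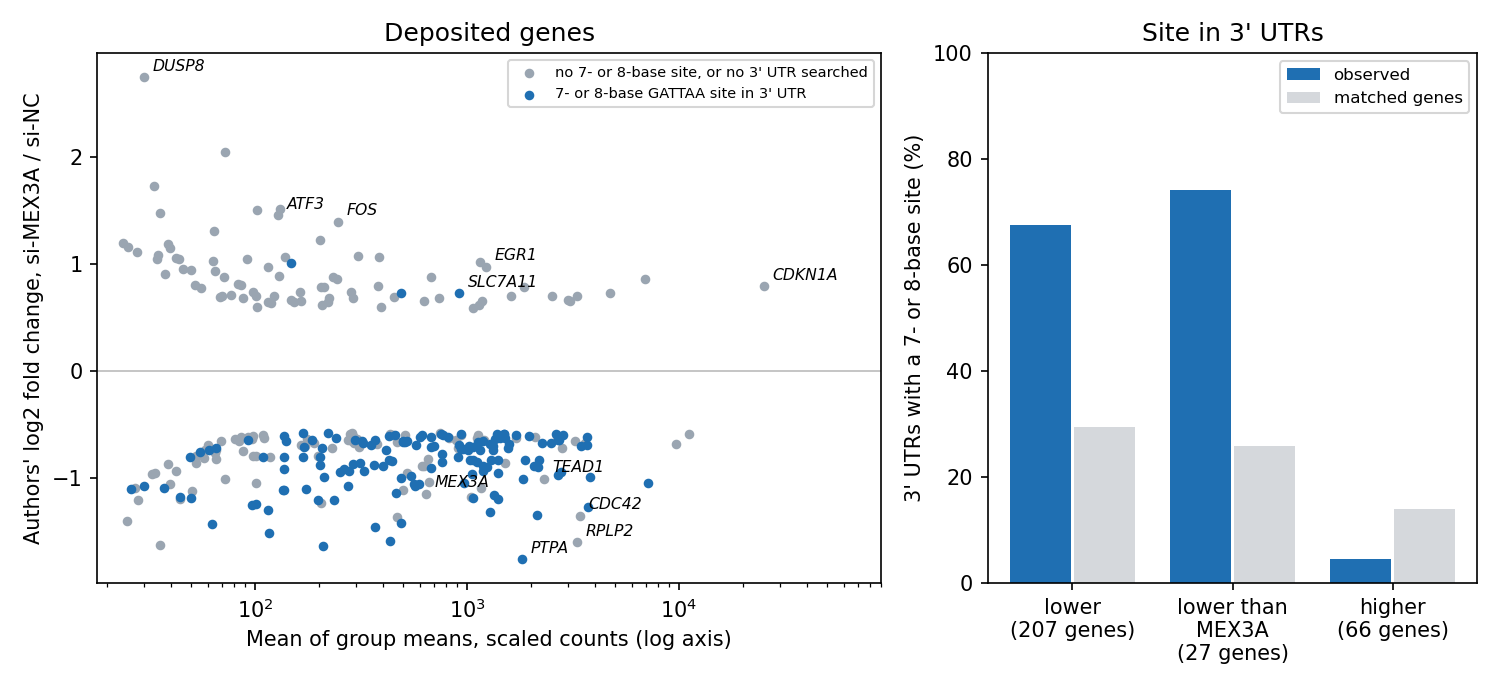
Left, deposited log2 fold change against the mean scaled count (log axis) of the 305 genes, in blue where the 3′ UTR holds AGATTAA or GATTAAA. Right, percentage of searched 3′ UTRs with either word in lower, below-MEX3A and higher genes (blue) and in matched genes (grey). The observed shares are 67.6%, 74.1% and 4.5%, against 29.5%, 25.9% and 14.1%.

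No member of 10 fixed lists was in the table. These were cholesterol and fatty acid synthesis, epithelial junction genes, Wnt targets and stem cell genes, TGF-beta and BMP targets, canonical histone genes, ribosomal protein genes by the fixed name rule (which leaves out RPLP2), mitochondrial genome genes, and markers of blood and immune cells, of fibroblasts and endothelium, and of other cultured lines. For these the table does not tell an unchanged gene from one that was not measured.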

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

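The threshold, filter, TMM, DESeq2 size factor, block and left-out-library settings were planned; no scaling, DESeq2 with the recovered factors, the lists under TMM, without si-NC replicate 3 or without site genes, and every setting for the 3′ UTR site were chosen after seeing the data. By edgeR's quasi-likelihood test all 305 genes passed (81 higher, 224 lower), as they must when chosen for differing. The count stayed at 305 to 305 on leaving out each library in turn, where MEX3A ranged from -1.18 to -1.11, and at 305 with the replicate block, no scaling or DESeq2 on the recovered factors; the block changed no call. Same-numbered libraries had correlations of 0.065, 0.007 and 0.109 over genes in their deviations from the group means, and not every library correlated best with its own number. A minimum mean count of 50 removed 13 genes, and edgeR's own filter removed 0 and so tests nothing. Asking for 2-fold left 80 genes (26 higher, 54 lower) and 1 fixed list past the threshold instead of 3. That list, the immediate early genes, was the only one with enough members left to test. The p53 and hypoxia lists kept 1 and 2 members and were not tested. Scaling on the listed genes themselves moved si-MEX3A against si-NC by 0.66 log2 units with TMM and 0.67 with DESeq2, because it takes the middle of a mostly lower table as unchanged. With TMM 155 genes passed (74 lower, 47.7% of calls) and with DESeq2 149 (68 lower, 45.6%), so the share of lower genes went below 50%, and TMM left 1 list past the threshold. The p53 and hypoxia lists kept all 3 members higher under TMM, but against a near-even split 3 of 3 higher cannot pass. MEX3A stayed lower (-0.49 and -0.48). Under TMM and DESeq2 scaling the log2 fold changes turned positive for CDC6 (0.0101 and 0.0174), ECT2 (0.003 and 0.0103), PARP14 (0.0386 and 0.0459), MIR600HG (0.0452 and 0.0525) and, under DESeq2 alone, HMMR (0.0002). CDC45 (0.06 and 0.07) and AC099850.3 (0.03 and 0.04), named outside the fixed rule, turned positive too. Of the other genes named by the rule none changed direction, 6 losing the call under TMM (E2F2, CLSPN, TOP2A, SDF2L1, BCL2 and HMMR) and the first 5 of these under DESeq2. CEBPG, CS and LONP1, named outside the rule, lost it too. Leaving out genes with a 7-base or 8-base site left 1 list past the threshold, the immediate early genes, with fewer genes tested. The p53 and hypoxia lists again kept all 3 members higher, which cannot pass against the near-even split that remained. The share of lower genes with a site stood 38.1 percentage points above matched genes, and 37.9 to 46.1 points above under the 4 other choices. An adjusted p of at most 0.01 left 305 genes and at least 1.5-fold by edgeR 303. Median centring, camera and the FPKM settings were not run, since the table holds counts of called genes only. Total depth is unknown, so no limit of detection is given.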

Other observations

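The tests of noise, of the control library, of handling, of the scale, of GATTAAA in higher genes, of the base before GATTAA and of the gene groups chosen here were set after the values were seen; the searches for 7-base words, for the MEX-3 recognition element and of 3′ UTR length were set before their results. Genes of mitochondrial proteins were mostly lower, 18 of 21 that were picked out after their values were seen. CS, which encodes citrate synthase, fell from 3076 ± 129 to 1922 ± 8.81 scaled counts, SUCLG2 from 889 ± 46.7 to 430 ± 5.78, CYCS, which encodes cytochrome c, from 3670 ± 118 to 1905 ± 129, and the protease gene LONP1 from 4544 ± 35.3 to 2805 ± 62.4 (SD, n = 3). With TMM and DESeq2 factors from the listed genes CS (-0.02 and -0.01) and LONP1 (-0.04 and -0.03) did not pass. ARG2, DHRS2 and ABCB6 were higher. The direction did not differ from that of the whole table (Fisher's exact test, p = 0.3). A 7-base or 8-base GATTAA site was in 10 of the 18, where 67.6% of all searched lower genes held one, so it does not set this group apart.

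Small GTPases and the Hippo pathway were lower in 10 of 11 picked genes, which also did not differ from the whole table (Fisher's exact test, p = 0.3). RAP1A fell from 635 ± 13.8 to 287 ± 44.2, ROCK2 from 2448 ± 96.7 to 1210 ± 37.0, YAP1, a transcriptional coactivator, from 2694 ± 47.3 to 1454 ± 39.9 and its partner TEAD1 from 3074 ± 132 to 1526 ± 106 scaled counts (SD, n = 3). RHOB was the exception and rose from 1917 ± 141 to 3106 ± 249. A site was present in 7 of the 10 lower genes, RAP1A, ROCK2 and YAP1 included, and TEAD1 had none. That is near the 67.6% of all searched lower genes.

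The first pattern is that 29 genes fell further than the target and that the lower genes share GATTAAA, against which counting noise and base composition were set: 10 of the 29 lay below MEX3A by more than the 95% interval of the difference, and, AGATTAA left out, 103 other words made of the same bases had a median z of 0.26 (highest 7.37, for AAGATTA, which overlaps AGATTAA). The higher genes, whose 3′ UTRs had more GC (median 47.3% against 37.3%), held GATTAAA in 3.0% where their own matched genes held it in 10.5% (z -2.16). The word was thus not in excess in the listed genes of both directions. Whether it is common to these cells' mRNAs was not measured. The matched genes were not limited to those expressed here, and the higher genes were picked by direction. A candidate explanation that stays open is off-target pairing of an siRNA seed (highest z 15.41), for which the prediction had asked that the top word also be in MEX3A, and GATTAAA is not. That absence does not decide the question, because AGATTAA shares the bases GATTAA with the top word. The 3′ UTR of MEX3A holds GATTAA once, with no A on either side. AAGATTA is in a MEX3A transcript on 1 strand or the other, as are 43.7% of all 7-base words. AGATTAA is in MEX3A once (bases 461 to 467 of the 6124-base transcript, coding part of exon 2 of 2, chromosome 1 from 156077670 to 156077676 on the minus strand of GRCh38), but so are 27.0% of all 7-base words, and among lower genes without GATTAAA the word TGATTAA, which is not in MEX3A, was in 18 of 78 against 5.5 expected, AGATTAA in 11 against 5.9. Loss of a protein that binds the MEX-3 recognition element was not decided, and the element was not counted in the higher genes. Lower genes without GATTAA held 179 matches against 153 expected (35 of 1000 random matched sets held as many, a resampling p of 0.036). All lower genes held 1899 against 1823 (73 of 1000, p of 0.074), short of the share under 0.05 that the prediction had asked for there too. Neither count ties the element to GATTAAA, so it was not shown that the element accounts for that word.

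The siRNA sequences were not used here, so the seed explanation was not tested against them. Another word, AGAGTAG, was picked from the same ranking over the lower genes (z 5.71, against a 95th percentile of 4.95 for the highest z in random sets). The resampling p-values that follow leave out that choice. AGAGTAG was in 50 lower genes against 24.9 expected (0 of 1000 random matched sets held as many, a resampling p of 0.001, the smallest that 1000 sets can give) and in 6 of the 27 genes below MEX3A against 2.4 (21 of 1000, p of 0.022). Among lower genes without GATTAA it was in 5 against 2.6 (93 of 1000, p of 0.094), and the MEX3A transcript holds it at bases 2723 to 2729 and 5897 to 5903.

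The second pattern is the joint rise of immediate early genes. A single low control library is argued against as the whole cause, since the difference of the group means of log2 counts was 0.802 without si-NC replicate 3 and 0.924 with it, over genes that were listed because they differed. The groups were 0.732 log2 units apart at their nearest libraries, which handling at transfection or harvest that differed between the groups would give as well as a response to the knockdown or to an off-target. These cannot be told apart here, because the labels give no batch, day or second siRNA. Of the 12 genes 1, FOSL2, held a GATTAA site of 7 bases.

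The third pattern is the excess of lower over higher genes. An error of scale would move genes with and without a GATTAA site alike. Of the 207 searched lower genes 140 held a 7-base or 8-base site, and the highest of 1000 random matched sets was 79. That comparison leaves out that the site was picked from these same genes. It argues against an error of scale as the only source of the lower genes. It cannot decide whether such an error made the whole excess in number, because real falls and a scale error can occur together. Searched genes without such a site numbered 67 lower and 63 higher (exact binomial test, p = 0.79). The site had been picked for its excess in the lower genes, so leaving out its holders had to shrink the lower side. This split therefore does not bear on the cause. As a part or the whole of the excess in number, an error of scale cannot be told apart from a true excess. A shift of 0.12 log2 units would make the numbers past 2-fold equal, and genes outside the table were not analysed here. Lower genes had longer 3′ UTRs, with a median of 1812 bases against 1215 (permutation test, p = 0.042), which is consistent with a part for 3′ UTR length, though longer 3′ UTRs also hold more sites.

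Of the 10 splits of the 6 libraries into 3 and 3, the real split, 1 of the 10, called 305 genes, and the highest other called 0 by edgeR (at most 1 gene at an unadjusted p under 0.05) and 0 by DESeq2. The splits are too few for a share under 0.05, and the genes had been chosen on the real split.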
